A study of Mus musculus with 139 samples.

How the data were processed

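Chromatin immunoprecipitation sequencing was done on mouse macrophages treated with KLA (100 ng/ml) for 1, 6, 12, 18, 24 or 48 h. Per the labels, inhibitors were added before KLA. Groups were taken from the labels. Reads were aligned with Bowtie 0.12.7 to mm9 and regions were called with HOMER, per the submitters' processing notes. No header of the lists names a control library in its command. Each list belongs to 1 sample, but some headers name combined directories, so a list may join several sequencing runs. The time-course H3K4me2 headers name micrococcal nuclease libraries.

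The deposited lists give, per the file headers, a signal for each region, the normalised tag count per 10 M tags, with the region's position. They also give a clonal fold, the ratio that HOMER uses to filter regions with many identical tags. Per the file headers the limit of that fold was 2, and the filter removed 45 regions of the untreated and 42 of the KLA 6 h time-course H3K4me2 library. A region also had to reach a Poisson tag threshold that rose with depth, 10 tags in the untreated, 14 in the KLA 6 h and 5 in the untreated siCtl library. Normalised tag counts gave whole tag numbers for 100% of regions in 95 libraries (tolerance 0.1 tags). Because regions were called separately in each library, no common count table exists, and count models were not used. Tag counts are the authors' values and served to describe, rank and filter regions. Total tags were taken from the headers.

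The region sets, the tests and the alternatives were fixed before the data were examined. Overlap was at least 1 bp. Gained regions were H3K4me2 regions of the KLA 6 h time-course library without overlap to the untreated library, constitutive regions overlapped it, and lost regions were untreated ones without a KLA 6 h counterpart. Induced p65 sites were KLA 1 h group 1 peaks overlapping group 2 and no untreated p65 peak. A region counted as called in another library where it overlapped a region there. A tag count given for another library is the total of that overlapping region, whose limits can differ. Density was the tag count per kb of the overlapping region, or 0 where none was called. The density ratio was log2 of the mean density over the set divided by that over constitutive regions of the same library, or for H4K8ac over constitutive regions without p65. No pseudocount was used.

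Paired siRNA comparisons used a two-sided exact sign-flip test of 9 differences, since the labels give 1 untreated and 1 KLA library per siRNA. The header of the siMll3 H3K4me2 library with KLA names a second replicate, which its untreated partner does not. siSmyd1 had no untreated library here and entered only the comparison of KLA libraries. Other groups were compared by two-sided exact permutation tests. Benjamini-Hochberg adjustment covered the 4 siRNA tests, and each added family was adjusted on its own, except the single H4K8ac test at strong gained regions. The tests of candidate explanations and the comparison of H3K4me2 with H3K4me1 in the closing section were not adjusted either. The exact permutation p cannot fall below 0.33 with 2 against 2 libraries, 0.0286 with 4 against 4 and 0.00833 with 3 against 7. Nothing in the labels says that replicates came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical. Group numbers 1 and 2 are shared between conditions and were not taken as pairs. Shares from single libraries have Wilson 95% intervals, which cover counting error only, and no p-value.

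A region was assigned to the protein-coding gene with the nearest start within 100 kb in the mm9 annotation (NCBIM37), and regions over 3 kb from any start were called distal. Lists of genes were fixed for inflammatory mediators, interferon response, NF-kB pathway, immediate early factors, macrophage identity, cholesterol and lipid metabolism, housekeeping, lymphocytes, granulocytes and mast cells, fibroblasts and mesothelium, and non-haematopoietic tissues. Each list was set against 10000 random gene lists matched on the number of untreated H3K4me2 regions. Genes were named by a rule: per set, the 10 regions with the highest tag count, and from each list up to 4 genes with the highest tag count in a region of the set. Unplaced and mitochondrial sequences were left out. Co-occupancy was set against 10000 random draws from all KLA 6 h regions, gained ones included, matched on 10 classes of tag density. An added version also matched on 5 classes of length.

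The alternatives were an overlap of at least 50% of the shorter region, a stricter set at or above the median tag count of the defining list, equal list length, the other measure, distal regions only, the replicate number as a block, and leaving out each library. Added later were a common tag minimum for the 3 inhibitor libraries of H3K4me2 (the Poisson threshold of each scaled to 10 M tags per 0.5 kb, with the highest applied to all), subtraction of matched constitutive regions, pairs with at least 2.5 M untreated tags, and H4K8ac at gained regions. Bootstrap intervals used 1000 draws.

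The method was tested on simulated data with 9 pairs and 4000 sites, 200 times per setting. Simulated differences of 0, 3 and 7 points gave mean estimates of 0.0190, 2.95 and 6.82 points, and 4.5%, 32% and 93% of simulations passed the unadjusted threshold of 0.05. The simulated pair differences spread less than the real ones (SD 6.82 points for H3K4me2 and 7.80 for H3K4me1) and held no depth difference. The shares passing at 3 and 7 points may therefore be too high for these data. Overlaps of 8000 regions were checked against bedtools 2.31.1, with 0 differences. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

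The lists labelled IBET151 and IKK inhibitor for H3K4me2 held the same 80570 regions, and both headers name the IKK inhibitor directory. They were counted as 1 library. The H4K5ac coordinates fit another build than mm9, not given in the sources used here, so those lists received no gene names. The amanitin labels disagree on the length of treatment, and the titles were followed. Nascent RNA and input samples were not analysed here.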

Results

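The series followed chromatin and transcription factor binding in mouse macrophages exposed to Kdo2-lipid A (KLA), the lipid part of bacterial endotoxin that activates Toll-like receptor 4. Most libraries came from thioglycollate-elicited peritoneal macrophages of male C57Bl/6 mice, and the H4K5ac libraries from bone marrow-derived macrophages. Of the 139 samples, 98 came with a list of enriched regions from chromatin immunoprecipitation sequencing and are described here. The other 41, nascent RNA and input libraries, were not analysed here. The lists covered the histone marks H3K4me1 and H3K4me2, which mark enhancers and promoters, the acetylation marks H3K27ac, H4K8ac and H4K5ac, and H3K27me3. They also covered the NF-kB subunit p65, the macrophage factors PU.1 and C/EBPa, and RNA polymerase II phosphorylated at serine 2. Library depth ranged from 0.903 to 28.0 M (mega) tags (median 7.10 M), and the number of regions from 369 to 114667. The siRNA series held 1 untreated and 1 KLA library per siRNA for H3K4me1 and H3K4me2, covering a control siRNA (siCtl) and 8 siRNAs named after H3K4 or other lysine methyltransferases. A further siRNA, siSmyd1, had KLA libraries and no untreated one here. Depth there ran from 1.20 to 9.81 M tags for H3K4me2 and from 4.30 to 10.2 M for H3K4me1. Most time points and inhibitor conditions had 1 library, and values from them have no replicate check.

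The time course asked where H3K4me2 appeared and disappeared after KLA. After 6 h of KLA, 21290 of 92528 H3K4me2 regions (23.0%, Wilson 95% interval 22.7 to 23.3) had no counterpart in the untreated list, and 2308 of 79899 untreated regions (2.89%, 2.77 to 3.01) had none after KLA. Gained regions were mostly weak and distal. Their median normalised tag count was 7.1 per 10 M tags against 42.4 at the 71238 constitutive regions, and 88.9% lay over 3 kb from a transcription start site against 75.7%. Inside the gene of the prostaglandin E synthase Ptges (intron, chromosome 2, 30767626 to 30773925, mm9), the gained region held 53.9 tags at 1 h, 237.5 at 6 h, 465.7 at 24 h and 236 at 48 h. The region 3794 bp from the start of Lad1 (chromosome 1, 137709260 to 137713502) held 23.1, 177.6, 68 and 38 tags at the same times. At Csf3, the granulocyte colony-stimulating factor gene, a region 39 bp from the start (chromosome 11, 98561424 to 98563652) held 10.3, 78.1, 165.2 and 85.2 tags. Near Il6, 39.6 kb away (39622 bp; chromosome 5, 30299118 to 30301040), the counts were 5.8, 41.7, 72.9 and 52.3. The interferon-inducible gene Gbp5 had 33.9 tags in an intronic region at 6 h and 1239.2 at 24 h (chromosome 3, 142172783 to 142175129). Coordinates are those at 6 h, and counts at other times belong to the overlapping region called then. A longer region alone can raise such a count. In the siRNA libraries at 6 h, the Csf3 region had 30.5 ± 13.5 tags per kb with KLA and 29.1 ± 25.9 without (SD, n = 9, exact p = 0.895), and the Gbp5 region was called in 0 of 9 libraries with KLA and 0 of 9 without. A region 44563 bp from Acsl1, a fatty acid activating enzyme, held 28.9 tags at 6 h, 339.4 at 24 h and 1012.7 at 48 h (chromosome 8, 47511197 to 47512467).

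Of the 10 gained regions with the highest tag counts, 8 lay at or near the starts of Fen1 (445.1 tags), Sart3 (444), Smc2 (384.5), Racgap1 (378.8), Zfp568 (372.7), Taf6 (357), Zfand1 (264.6) and Kif14 (191.2). Each of these 8 was also called in 9 of 9 untreated siRNA libraries for H3K4me2, so their absence was particular to the untreated time-course list. The same held for lost regions with high counts, at Ankmy2 (742.6 untreated tags), Paxip1 (481.8), Qpctl (458.9), Cenpn (369.3), Tbl2 (314.6) and Pdcd7 (276.6), which were called in each KLA siRNA library. Leaving out the 51 gained regions called in every untreated siRNA library left 21239.

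Among gene lists fixed in advance, 14 of 20 interferon response genes had a gained H3K4me2 region within 100 kb, which placed the list at percentile 99.3 of 10000 random lists matched on untreated regions. Random lists drew genes singly, while this list holds neighbours such as Mx1 and Mx2, so the percentile may be overstated. Percentiles were not corrected for the number of lists. For NF-kB pathway and feedback genes the number was 16 of 22 (percentile 87.1), and for inflammatory cytokines and mediators 16 of 24 (72.7). Immediate early transcription factors had 11 of 16 (25.5), macrophage identity genes 14 of 19 (47.0) and cholesterol and lipid genes 9 of 16 (16.1). Housekeeping genes had 4 of 14 (5.77). Markers of other cells had 5 of 13 for T and B lymphocytes (68.7), 6 of 13 for granulocytes and mast cells (88.2) and 4 of 9 for fibroblasts and mesothelium (49.7). Genes of non-haematopoietic tissues had 4 of 11 (78.2), and all protein-coding genes 39.0%. In the interferon list, the antiviral GTPase gene Mx1 had 106.3 tags in an intronic region at 6 h (chromosome 16, 97670000 to 97677090), and Ifit3 had 77 (intron, chromosome 19, 34658513 to 34661050). In the NF-kB list, Nfkbiz had 94.2 tags 10695 bp away, inside an intron of Fam55c (chromosome 16, 55847542 to 55851873) and the intronic Nfkb1 region 81.7 (chromosome 3, 135302042 to 135304860). Tnfaip3, which encodes the NF-kB inhibitor A20, had 73.1 tags in a distal region (chromosome 10, 18826983 to 18829106). Lost regions were near 1 of 24 inflammatory genes (Il10), 0 of 20 interferon genes and 1 of 22 NF-kB genes (Nfkbiz), at percentiles 4.95, 9.37 and 4.62. Housekeeping genes, with 0 of 14 (percentile 9.7), and macrophage genes, with 2 of 19 (11.1), also ranked low. Lost regions were near 3 of 16 immediate early (36.1), 3 of 16 cholesterol (52.0) and 1 of 13 lymphocyte genes (67.1). They were near 0 of 13 granulocyte (20.0), 1 of 9 fibroblast (64.1) and 0 of 11 non-haematopoietic genes (35.2).

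The other times gave 9915 gained and 5772 lost regions at 1 h, 11234 and 11356 at 24 h, and 11766 and 13414 at 48 h. Regions gained at 6 h were called in 31.8% of cases at 1 h, 34.5% at 24 h and 32.4% at 48 h, while 77.9% of those gained at 1 h were called at 6 h. The 6 h library was also the deepest, with 28.0 M tags against 12.6 M untreated and 9.75 to 15.6 M at the other times. With both lists limited to the same number of strongest regions, 11148 regions were gained at 6 h. A stricter set, planned in advance, kept gained regions at or above the median tag count of the 6 h list and held 634, called strong gained regions here.

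**Figure D1:**
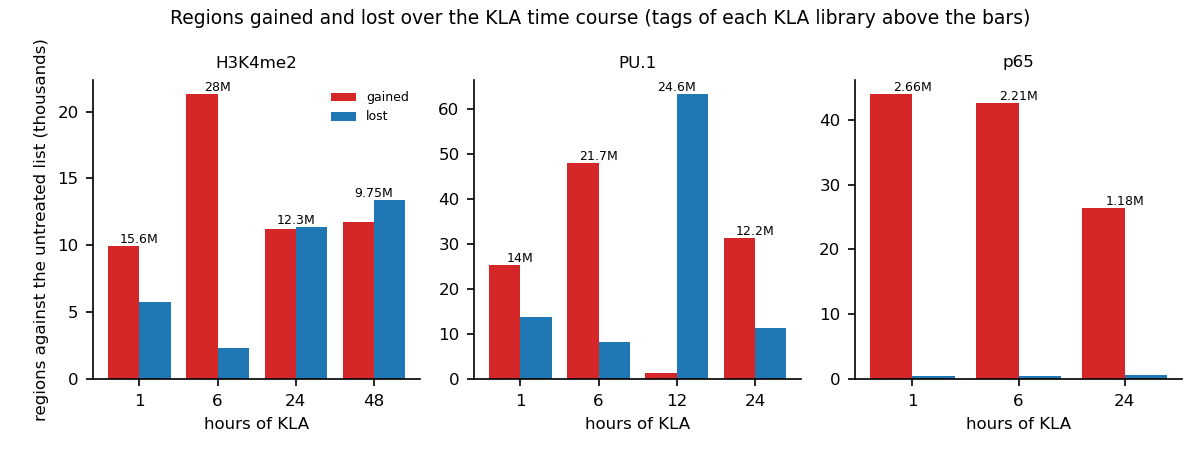
Numbers of regions (axis in units of 1000) gained and lost against the untreated list for H3K4me2, PU.1 and p65 by hours of KLA, 1 library per time, with the depth of each KLA library in M tags above the bars. H3K4me2 gains were highest at 6 h (21290), in the deepest library, and the PU.1 library at 12 h had 13182 peaks in all.

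Libraries from siRNA-treated macrophages, which had no part in defining the sets, asked whether gained regions carried H3K4me2 and H3K4me1 after 6 h of KLA. At the 634 strong gained regions, H3K4me2 rose with KLA: 64.3% ± 10.6 of them (SD, n = 9 siRNAs) were called with KLA and 25.3% ± 10.9 without. The increase was 39.1 points, in 9 of 9 pairs (two-sided exact sign-flip test, p = 0.00391, the smallest 9 pairs allow; adjusted p = 0.00781 over 4 siRNA tests). H3K4me1 rose from 39.8% ± 6.52 to 75.8% ± 8.48 (SD, n = 9), in 9 of 9 pairs (exact p = 0.00391, adjusted 0.00781). At all 21290 gained regions, the planned main set, H3K4me2 was called at 19.6% ± 5.56 with KLA and 12.6% ± 6.06 without (8 of 9 pairs higher). That difference of 6.99 points (SD of the differences 6.82) had an exact p of 0.0195 and missed the threshold after adjustment over 4 tests (n = 9 pairs, adjusted p = 0.0547). H3K4me1 was called at 31.3% ± 6.59 against 23.6% ± 4.65 (7 of 9 pairs higher; difference 7.77 points, SD 7.80; n = 9, exact p = 0.0273, adjusted 0.0547). The paired KLA libraries for H3K4me2 were deeper (median 3.95 against 2.67 M tags). At all gained regions, every pair that fell had a KLA library shallower than its untreated partner. For H3K4me2 this was siSetd7 (1.91 against 3.43 M tags). For H3K4me1 these were siMll1 (6.95 against 7.18 M) and siSetd7 (6.79 against 7.72 M). With shallower KLA libraries, siMll1 for H3K4me2 and siMll2-4 for H3K4me1 still rose. The direction of a pair thus went in part with depth. At equal list length the H3K4me2 difference was 3.26 points (n = 9 pairs, exact p = 0.00391), and in the 5 pairs with at least 2.5 M untreated tags it was 3.86 (exact p = 0.312).

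**Figure D2:**
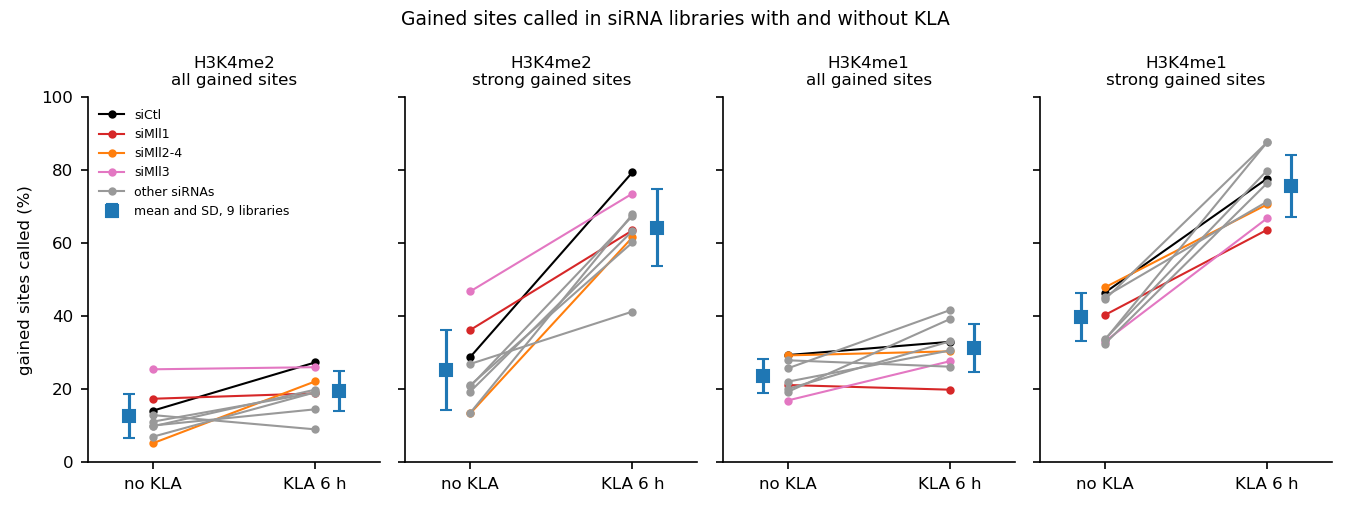
Percent of gained regions called in H3K4me2 and H3K4me1 libraries without and with 6 h of KLA, for all 21290 and for the 634 strong gained regions; each line is 1 siRNA pair and squares with bars give mean and SD of 9 libraries. At strong regions H3K4me2 goes from 25.3% to 64.3% and H3K4me1 from 39.8% to 75.8%, with each of the 9 lines rising.

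Regions near genes of the inflammatory lists gained both marks in the siRNA libraries. H3K4me2 rose at the 68 gained regions near inflammatory cytokines and mediators, from 13.7% ± 10.7 called without KLA to 31.2% ± 11.7 with it (SD, n = 9). It rose at 28 regions near interferon response genes, from 7.14% ± 5.05 to 30.2% ± 13.5, and at 52 near NF-kB genes, from 11.5% ± 7.00 to 34.8% ± 12.6. Each was higher in 8 of 9 pairs (exact sign-flip, adjusted p = 0.0391 over 10 lists). H3K4me1 rose at the same regions, from 20.3% ± 6.40 to 39.7% ± 9.67, from 12.7% ± 5.68 to 54.8% ± 14.5 and from 24.8% ± 6.41 to 52.6% ± 10.1, in 9 of 9 pairs each (n = 9, exact adjusted p = 0.0130). H3K4me1 also rose near immediate early transcription factors, from 27.4% to 40.7% in 8 of 9 pairs (exact adjusted p = 0.0195), and near cholesterol and lipid genes, from 36.4% to 59.1% in 8 of 9 pairs (exact adjusted p = 0.0234). Macrophage identity genes had 38.6% against 30.8% (exact adjusted p = 0.0521). The housekeeping, lymphocyte, granulocyte and fibroblast lists did not pass for either mark; H3K4me1 was called at 29.6% against 23.5%, 33.3% against 26.7%, 20.4% against 15.7% and 16.7% against 15.3%. For H3K4me2 the remaining lists had 29.1% against 17.0% (immediate early), 28.8% against 18.7% (macrophage), 32.3% against 19.2% (cholesterol), 22.2% against 13.6% (housekeeping), 22.2% against 16.7% (lymphocyte), 14.8% against 8.33% (granulocyte) and 43.1% against 45.8% (fibroblast), with adjusted p from 0.0781 to 0.828 by the exact test. These list tests, 39 with those for H4K8ac, were added after the main values were seen. Leaving out the pair of siCtl, siMll1, siMll2-4, siSet1a, siSet1b, siSmyd2 or siSmyd3 raised the adjusted p of the 3 H3K4me2 lists to 0.0781 and leaving out siMll3 raised it to 0.0521, while H3K4me1 near cholesterol genes was lost with overlap of at least 50% of the shorter region (exact adjusted p = 0.0625) or density as the measure (0.0547).

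**Figure D3:**
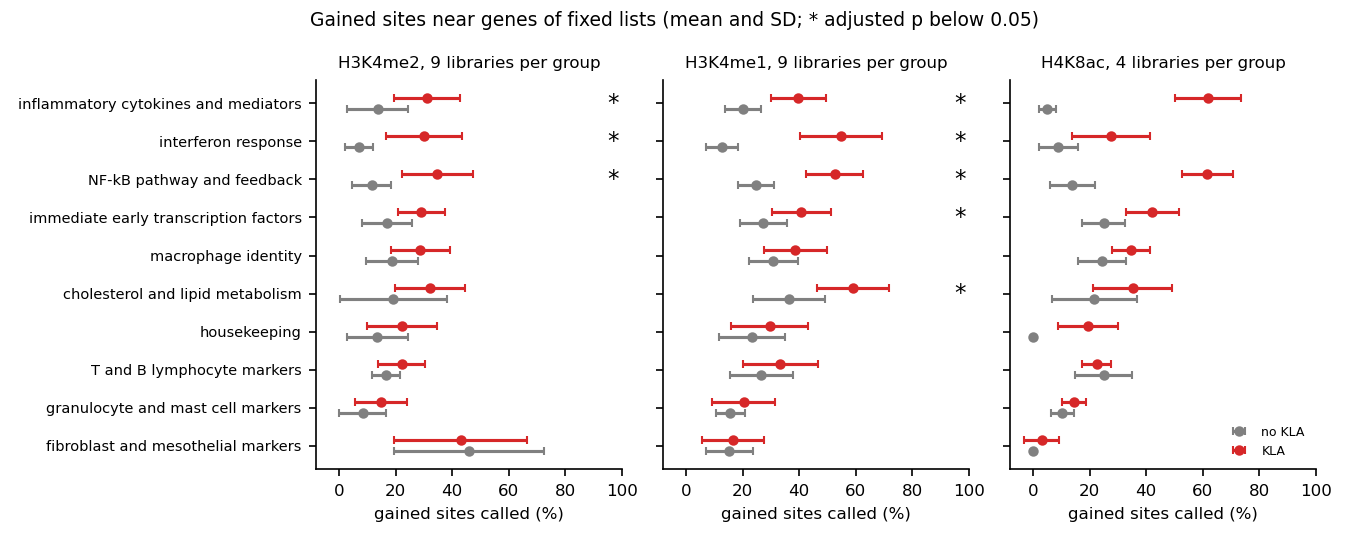
Percent of gained regions near genes of 10 fixed lists called with KLA (red) and without (grey), as mean and SD, for H3K4me2 and H3K4me1 (9 libraries per group) and H4K8ac (4 per group); asterisks mark adjusted p below 0.05. The inflammatory, interferon and NF-kB lists pass for both methylation marks, with H3K4me1 at interferon genes going from 12.7% to 54.8%.

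Single gained regions were tested for H3K4me2 density in the same libraries, 54 in all, after the main values were seen. The region near Ch25h, the cholesterol 25-hydroxylase gene (chromosome 19, 34525261 to 34526056), was called for H3K4me2 in 9 of 9 siRNA libraries with KLA and 0 of 9 without, at 36.6 ± 17.2 tags per kb with KLA (SD, n = 9, exact p = 0.00391, adjusted 0.0527). The Tnfaip3 region was called in 9 and 3 of 9 libraries (37.5 ± 9.62 against 8.50 ± 13.1 tags per kb), and the Ifit3 region in 9 and 5 (55.6 ± 9.63 against 17.6 ± 18.3). Near Tlr2, the bacterial lipopeptide receptor gene, a region (chromosome 3, 83679544 to 83681063) was called in 9 and 3 of 9 libraries, at 46.9 ± 13.5 against 11.9 ± 18.4 tags per kb. These 3 had the same exact p and adjusted p as Ch25h. The Lad1 region had 36.8 ± 9.42 against 5.58 ± 16.7 tags per kb (n = 9, exact p = 0.00781, adjusted 0.0603). Near Klf6 the density was lower with KLA (30.1 ± 16.0 against 49.6 ± 21.03; n = 9, exact p = 0.00781, adjusted 0.0603). Other regions named above were called with and without KLA in 9 and 6 of 9 libraries (Ptges), 8 and 6 (Csf3), 7 and 3 (Nfkbiz), 6 and 4 (Il6), 6 and 0 (Acsl1), 4 and 0 (Mx1) and 0 and 0 (Gbp5). At an unadjusted exact p under 0.05, 8 of the 54 regions were higher with KLA and 3 lower, and 0 passed adjustment.

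The 3 siRNAs against Mll methyltransferases (siMll1, siMll2-4 and siMll3) were compared with the 7 others for H3K4 methylation at gained regions. Of those 7 only siCtl is a control, and the rest are named after other methyltransferases. The degree of knockdown was not analysed here, since region lists hold no transcript levels. The header of the siMll3 H3K4me2 library with KLA names a second replicate, so it may come from another replicate than its untreated partner. At strong gained regions with KLA, H3K4me2 was called at 63.6% with siMll1, 61.7% with siMll2-4 and 73.7% with siMll3. The 7 other libraries lay between 41.3% (siSetd7) and 79.5% (siCtl). H3K4me1 was called there at 63.7%, 70.7% and 66.9%, against 77.8% with siCtl and 67.5% (siSmyd1) to 87.7% over the 7 others. The siMll1 and siMll3 shares lay below each of the 7 others, and siMll2-4 above siSmyd1 only. The siMll1 and siMll3 libraries for H3K4me1 were also the least enriched. They had 22.9% and 24.9% of tags in peaks, against 31.9% to 42.7% in the 7 others. The siMll2-4 library had 44.0%. Low enrichment can lower a share called and was not separated from the siRNA. These shares were not tested, and the density tests that follow do not settle whether they differ. A loss common to gained and constitutive regions cancels in the density ratio. The tests therefore ask only whether the Mll libraries stand apart at gained relative to constitutive regions. They cannot show whether methylation depended on the Mll enzymes. As density relative to constitutive regions, the Mll difference at strong regions was 0.0021 for H3K4me2 (n = 3 and 7, exact permutation p = 1) and -0.08 for H3K4me1 (exact permutation p = 0.408, adjusted 0.544). Over all gained regions, the H3K4me2 density relative to constitutive regions was -2.0 ± 0.14 on the log2 scale in the 3 Mll libraries and -2.26 ± 0.25 in the 7 others (SD; difference 0.26, two-sided exact permutation p = 0.158, adjusted 0.211). For H3K4me1 it was -1.50 ± 0.16 against -1.34 ± 0.17 (n = 3 and 7; difference -0.15, exact permutation p = 0.233, adjusted 0.233). The H3K4me2 difference turned to -0.04 (exact permutation p = 0.917) with each siRNA's untreated level subtracted and to -0.11 against siCtl alone. By gene list, H3K4me1 at regions near macrophage identity genes was called at 27.3% ± 8.19 in the Mll libraries and 43.2% ± 7.54 in the others (n = 3 and 7, exact permutation p = 0.0167, adjusted 0.267 over 20 tests). The low enrichment of the siMll1 and siMll3 libraries applies to this share too. H3K4me2 near cholesterol genes was called at 43.9% ± 6.94 and 26.6% ± 9.25 (n = 3 and 7, exact permutation p = 0.0333, adjusted 0.267). None of the 20 list tests, added after the main values were seen, passed adjustment.

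Binding of p65 was compared with and without KLA. The KLA 1 h libraries of groups 1 and 2 had 45491 and 52812 peaks, while the untreated ones had 1955 and 5008, from 1.25 and 7.65 M tags, and mean log2 peak numbers were 15.58 ± 0.15 and 11.61 ± 0.96 (SD, n = 2). The difference of 3.97 had an exact permutation p of 0.33, the smallest that 2 against 2 allow. Sites bound in both KLA libraries and in neither untreated one numbered 31883 (induced p65 sites; median 45.1 tags, 65.2% over 3 kb from a start). All 24 inflammatory genes had an induced site within 100 kb (percentile 100 of 10000 matched random lists), and 20 of 22 NF-kB genes did (99.1). Housekeeping genes had 12 of 14 (98.9), macrophage identity genes 18 of 19 (91.5), immediate early factors 15 of 16 (89.2), interferon genes 14 of 20 (86.8) and cholesterol genes 14 of 16 (85.7). Lymphocyte markers had 7 of 13 (86.2), granulocyte markers 4 of 13 (27.2), fibroblast markers 3 of 9 (5.49) and non-haematopoietic genes 2 of 11 (12.3). The strongest inflammatory site lay 864 bp from Il23a, which encodes a subunit of interleukin-23 (chromosome 10, 127735937 to 127736071), with 563.3 tags in group 1 and 381.3 in group 2. Sites near Cxcl1 (506.9 tags, chromosome 5, 91305228 to 91305362), Ccl5 (473.1, chromosome 11, 83349773 to 83349907) and Ccl2 (461.9, chromosome 11, 81846651 to 81846785) followed. The strongest NF-kB pathway sites were near Socs3 (525.7), in Nfkb2 (469.4), near Nfkbia (435.6) and near Cd40 (435.6). Fos had 552 tags at a site 38962 bp away, and the strongest sites of all were near Fbxo11 (833.6, chromosome 17, 88511756 to 88511890) and in introns of Sept11 (822.3) and Rbl2 (792.3). Of the peaks gained at 1 h, 67.1% were called at 6 h and 42.9% at 24 h, in libraries of 2.21 and 1.18 M tags.

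Factors and marks were then placed on the H3K4me2 sets, with 1 library each. A p65 peak at KLA 1 h lay on 12.7% of gained regions (Wilson 95% interval 12.3 to 13.2), 38.9% of constitutive regions (38.6 to 39.3) and 2.38% of lost regions (1.84 to 3.09). Regions drawn from the whole KLA 6 h list, gained ones included, to match in tag density carried p65 at 10.0%. Gained regions stood at percentile 100 of the 10000 draws. Strong gained regions carried p65 at 70.2% (66.5 to 73.6) and before KLA at 0.631% (0.246 to 1.61). Relative to all constitutive regions, weak ones included, the share with KLA was 180% there and 32.6% over all gained regions. The 180% is not a matched value, since p65 at constitutive regions matched to the strong ones was not computed. PU.1 lay on 14.4% of gained regions before KLA and 30.2% at 6 h, against 57.7% and 69.9% of constitutive regions. In such draws matched on density the PU.1 shares were 22.2% and 36.3%. Gained regions stood at percentile 0 of the draws untreated, at 1 h and at 6 h, also with matching on length. At strong gained regions PU.1 covered 16.9% (14.2 to 20.0) before KLA and 60.1% (56.2 to 63.8) at 6 h. C/EBPa covered 6.20% of gained regions before KLA and 12.9% after 1 h, and H3K27ac 5.89% and 15.9%. At strong gained regions H3K27ac covered 10.9% (8.69 to 13.5) before and 74.8% (71.2 to 78.0) after 1 h of KLA. H3K27me3, a mark of repressed chromatin, covered 10.3% of gained and 14.5% of constitutive regions before KLA. Matching on length as well as density took H4K8ac, C/EBPa and H3K27ac after KLA from percentiles 0, 0 and 76.9 to 100.

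H4K8ac was compared at these sites after 1 h of KLA. At the 31883 induced p65 sites, its density relative to constitutive regions without p65 was 1.88 ± 0.31 on the log2 scale with KLA and 1.52 ± 0.20 without (SD, n = 4 each). The difference of 0.36 did not pass (two-sided exact permutation p = 0.143; smallest possible 0.0286). The density at induced sites itself was 54.7 and 50.7 tags per kb without KLA and 47.2 and 52.3 with it in the DMSO experiments, and 26.0 and 30.9 against 25.3 and 30.7 in the amanitin experiments. Reference densities were lower with KLA, 10.6 and 11.9 with KLA against 16.6 and 16.3 without, and 7.83 and 10.5 against 9.59 and 12.8. The share of induced sites called was 76.6% ± 9.83 with KLA and 68.9% ± 8.97 without (n = 4 each, exact permutation p = 0.286), or 83.3% against 73.5% in the DMSO and 69.8% against 64.3% in the amanitin experiments. Within the DMSO experiments the difference in ratio was 0.47 and within the amanitin experiments 0.26 (n = 2 against 2 each). In each series both KLA libraries lay above both libraries without KLA. The pooled test did not take the series into account. At the 21290 gained H3K4me2 regions the density was -0.72 ± 0.09 with KLA and -2.14 ± 0.32 without, 1.42 higher (n = 4 each, exact permutation p = 0.0286, the smallest possible; adjusted 0.257 over 9 tests). Most of those 9 tests set 2 against 2 libraries and could not fall below 0.33. An adjusted p under 0.05 was therefore out of reach in this family. At the gained regions the 2 series of experiments gave 1.67 and 1.17. The density itself was 7.06 and 6.81 against 3.49 and 2.93 tags per kb, and 4.60 and 6.42 against 2.21 and 3.90. Strong gained regions carried H4K8ac at 78.6% ± 5.45 with KLA and 15.1% ± 4.81 without (n = 4, exact permutation p = 0.0286, a single added test outside the 9 and not adjusted), and constitutive regions differed by -1.18 points (exact permutation p = 0.657). These tests at H3K4me2 sets were added after the main values were seen. Near inflammatory genes H4K8ac was called at 61.8% ± 11.6 of gained regions with KLA and 5.15% ± 3.06 without, and near NF-kB genes at 61.5% ± 9.02 and 13.9% ± 7.91 (n = 4 each, exact permutation p = 0.0286, adjusted 0.0952). Interferon regions had 27.7% ± 13.8 and 8.93% ± 6.84 (n = 4, exact permutation adjusted p = 0.171). The 9 housekeeping regions had 19.4% ± 10.6 and 0%, with the same p and adjusted p as the inflammatory list (exact permutation p = 0.0286, adjusted 0.0952). An adjusted p under 0.05 would have needed most lists at that smallest p. At induced p65 sites near inflammatory genes the values were 89.6% ± 6.66 and 48.0% ± 10.2, and near NF-kB genes 83.0% ± 11.1 and 53.8% ± 7.52 (n = 4, exact permutation adjusted p = 0.129).

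H4K8ac was also compared at 49 single induced p65 sites, after the main values were seen. Near Irf1, an interferon regulatory factor (chromosome 11, 53574894 to 53575028), the density was 86.7 ± 11.9 tags per kb in 4 KLA libraries and no region was called in the 4 without KLA. At Ifnb1, which encodes interferon beta (chromosome 4, 88168719 to 88168853), it was 48.4 ± 17.3 with KLA and again not called without. Near Ccl5 the density was 135 ± 62.6 against 20.6 ± 14.1, near Ccl2 83.4 ± 31.1 against 16.0 ± 19.2 and near Il23a 113.1 ± 71.4 against 38.2 ± 9.83. The site near Fos had 72.8 ± 52.4 and was not called without KLA, the one near D10Jhu81e had 90.0 ± 51.1 against 10.0 ± 11.6, and the one near Tlr2 118.7 ± 61.4 against 43.2 ± 8.24. Values were lower with KLA at Cd4 (15.9 ± 11.3 against 36.7 ± 6.94) and near Cd2 (22.0 ± 15.4 against 39.3 ± 6.04), which are lymphocyte markers. Each of these had the smallest possible p (n = 4 each, exact permutation p = 0.0286, adjusted 0.0933 over 49 regions). At that level 13 regions were higher and 2 lower, and 0 passed adjustment. With 4 against 4 libraries adjustment could be passed only if most regions reached that p, here and at the gained regions below. Near the chemokine gene Cxcl1 the values were 84.5 ± 47.4 against 52.8 ± 11.2, and near Isg15 104.2 ± 34.8 against 72.1 ± 29.8 (n = 4 each, exact permutation p = 0.343 and 0.2). At gained H3K4me2 regions, 12 of 54 were higher and 1 lower before adjustment and 0 after, among them Ptges (119 ± 50.3 against 11.5 ± 13.5 tags per kb), Tnfaip3 (40.9 ± 1.93 against 6.74 ± 13.5) and Csf3 (34.2 ± 9.03 against not called; n = 4 each, exact permutation p = 0.0286, adjusted 0.119).

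Inhibitors of transcription elongation were given before KLA to ask whether H4K8ac depended on it. Alpha-amanitin (10 µg/ml) blocks RNA polymerase II, and flavopiridol (1 µM) inhibits the elongation kinase CDK9. With amanitin and KLA the H4K8ac density ratio at induced p65 sites was 1.86 ± 0.01, against 1.62 ± 0.11 with KLA alone in the same experiments (SD, n = 2; difference 0.25, exact permutation p = 0.33, the smallest possible). With flavopiridol it was 2.66 ± 0.03 against 2.14 ± 0.01 with DMSO (n = 2; difference 0.51, exact permutation p = 0.33). The single flavopiridol library without KLA was not part of this comparison. All libraries compared had KLA, so these ratios do not show whether an inhibitor shifted H4K8ac without KLA. These ratios also moved with the reference: the density at induced sites was 51.4 and 52.5 tags per kb with flavopiridol against 47.2 and 52.3, and at reference regions 8.24 and 8.21 against 10.6 and 11.9. With amanitin it was 25.7 and 32.7 against 25.3 and 30.7, and at reference regions 7.11 and 8.94 against 7.83 and 10.5. As a share of sites called, the flavopiridol difference had the other sign: 73.7% ± 5.56 against 83.3% ± 4.03 (n = 2, exact permutation p = 0.33). At gained H3K4me2 regions the density ratios were -0.55 with amanitin against -0.74, and -0.58 with flavopiridol against -0.70. With flavopiridol the density itself was lower there, 6.06 and 5.01 against 7.06 and 6.81 tags per kb, and the share called was 12.9% against 20.5% (n = 2, difference -7.64 points, exact permutation p = 0.33). The share of constitutive regions called differed by -11.2 points (n = 2, exact permutation p = 0.33), so a drop was also seen there. It started from a higher share, 61.0% against 24.1% of gained regions in the DMSO group 1 library with KLA. Whether the drop relative to that share differed was not tested. In single libraries with the BET bromodomain inhibitor IBET151 (1 µM), the ratio at induced p65 sites was 2.62 with KLA and 2.13 without, against 2.15 and 1.72 in the DMSO group 1 libraries. The density at those sites was 61.8 and 54.8 tags per kb, and at reference regions 10.0 and 12.5.

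**Figure D4:**
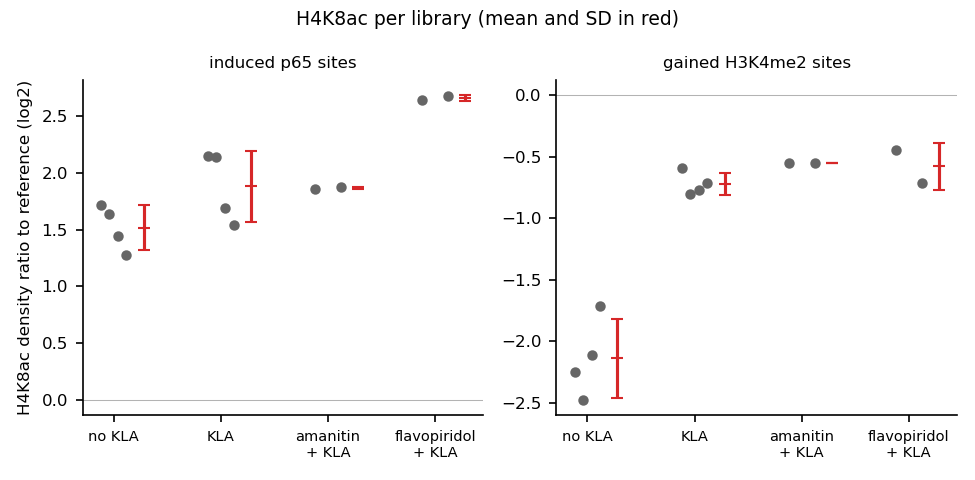
H4K8ac density relative to constitutive H3K4me2 regions without p65 (log2), 1 point per library, at induced p65 sites and at gained H3K4me2 regions, for no KLA and KLA (4 libraries each) and for amanitin or flavopiridol before KLA (2 each). At gained regions the KLA libraries lie between -0.80 and -0.59 and the libraries without KLA between -2.48 and -1.71.

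For H3K4me2, flavopiridol and an IKK inhibitor (30 µM), which blocks the kinase upstream of NF-kB, were given before 6 h of KLA, with 1 library each. At the 634 strong gained regions, 90.1% were called with DMSO (Wilson 95% interval 87.5 to 92.2), 43.5% with flavopiridol (39.7 to 47.4) and 51.3% with the IKK inhibitor (47.4 to 55.1). Constitutive regions matched to them in tag density and length were called at 88.2%, 80.9% and 88.8%. Near interferon genes, 11 of 28 gained regions were called with DMSO, 1 with flavopiridol and 3 with the IKK inhibitor. The numbers were 25, 6 and 14 of 68 near inflammatory genes and 23, 10 and 18 of 52 near NF-kB genes. The Ptges region held 176.2, 23.7 and 91.2 tags. The Ifit3 region had 118.8 tags with DMSO and was not called with either inhibitor, and the Nfkbiz region had 55.3, 11.9 and 10.5. The region 38803 bp from Fos had 48.1, 51.4 and 52.6. Near immediate early genes 9, 4 and 21 of 45 were called, near macrophage identity genes 8, 2 and 21 of 44, and near cholesterol genes 5, 3 and 6 of 22. The smaller lists had 3, 0 and 2 of 9 (housekeeping), 3, 2 and 1 of 10 (lymphocyte), 1, 2 and 3 of 12 (granulocyte), 1, 1 and 0 of 8 (fibroblast), and 0, 2 and 2 of 4 (non-haematopoietic). Over all gained regions 19.6% (19.0 to 20.1) were called with DMSO, 9.91% (9.52 to 10.3) with flavopiridol and 30.2% (29.6 to 30.9) with the IKK inhibitor, so the IKK inhibitor stood at 155% of DMSO over all gained regions and 56.9% at the strong ones. Constitutive regions matched to all gained regions were called at 27.9%, 20.0% and 48.5%, which put the IKK inhibitor at 173.96% of DMSO there, above its value at gained regions. The IKK inhibitor library stood apart in other ways: it called 31.3% of lost regions (29.4 to 33.2), against 9.36% with DMSO (8.24 to 10.6) and 6.02% with flavopiridol. It also held 568.5 tags at the neutrophil elastase gene Elane, where the KLA 6 h library held 9.3. These counts are totals of separately called regions, whose lengths were not compared. The deposited lists under the IBET151 and IKK inhibitor labels were identical, with 80570 regions, and were treated as 1 IKK inhibitor library; the label of that library therefore rests on its header.

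**Figure D5:**
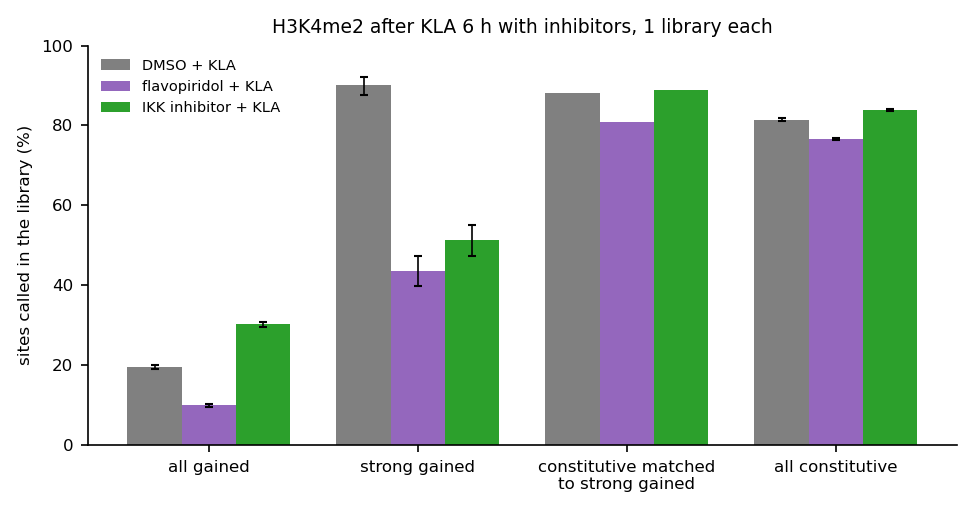
Percent of H3K4me2 regions called after 6 h of KLA with DMSO, flavopiridol or the IKK inhibitor (1 library each) at all gained, strong gained, matched constitutive and all constitutive regions; bars on the columns are Wilson 95% intervals of counting error, except at matched regions. Strong gained regions go from 90.1% with DMSO to 43.5% and 51.3%, and matched constitutive regions from 88.2% to 80.9% and 88.8%.

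In the amanitin experiments, H3K4me2 was called at 6.93% ± 0.521 of gained regions after 1 h of KLA and 2.90% ± 1.02 without (SD, n = 2; difference 4.03 points, exact permutation p = 0.33, the smallest possible). At the strong gained regions the difference was 59.7 points (n = 2). Amanitin with KLA gave a gained-region density of -4.14 ± 0.04 on the log2 scale, against -4.14 ± 0.10 with KLA alone (n = 2, exact permutation p = 1).

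PU.1 peaks were followed over the same time course. At 6 h of KLA, 47931 of 114667 PU.1 peaks (41.8%, Wilson 95% interval 41.5 to 42.1) were absent from the untreated list, and 8330 of 75066 untreated peaks were absent at 6 h. The strongest gained peaks near listed genes lay 51 bp from Ccl5 (236.3 tags, chromosome 11, 83343975 to 83344167), near Socs3 (197.6, chromosome 11, 117839176 to 117839368), near Dusp1 (152.9) and near Edn1 (150.6). At the Ccl5 start the counts were 134.2 at 1 h, 236.3 at 6 h and 177.1 at 24 h. Peaks near Tnf (109.1 tags), Il1a (82), Cxcl10 (79.7) and Tlr2 (58.9) followed, and so did an intronic peak of Ralgds (237.2), the highest of all. H3K4me2 without KLA covered 37.1% of gained and 77.0% of earlier PU.1 peaks, and a p65 peak covered 10.5% and 30.2%. Gained peaks lay near 17 of 20 interferon genes (percentile 91.9 of matched lists), 19 of 24 inflammatory genes (27.4) and 19 of 22 NF-kB genes (73.5). Markers of other cells also had them, with 10 of 13 lymphocyte (97.3), 9 of 13 granulocyte (95.9), 8 of 9 fibroblast (90.4) and 6 of 11 non-haematopoietic genes (70.9). Immediate early factors had 13 of 16 (11.6), macrophage identity genes 16 of 19 (15.0), cholesterol genes 14 of 16 (58.5) and housekeeping genes 10 of 14 (47.9). The other times gave 25401 gained peaks at 1 h and 31388 at 24 h. The 12 h library had 13182 peaks and an enrichment of 1.23% of tags in peaks despite 24.6 M tags, and the 6 h library was deeper than the untreated one (21.7 against 12.3 M). The stricter set left 6915 gained peaks and equal list length 15810.

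Inhibitors were also tested on factor binding, with 1 library per condition. Of 101667 PU.1 peaks with DMSO and 6 h of KLA, 38.3% were called again with flavopiridol. PU.1 peaks gained at 6 h of KLA were called at 49.1% with DMSO and 6.64% with flavopiridol, against 92.6% and 52.7% for peaks present before KLA. With IBET151 at 1 h of KLA, 35.6% of 63321 PU.1 peaks were called again, at 16.8% and 2.21% of gained and 73.0% and 32.5% of earlier peaks. The median log2 ratio of tag counts at peaks called in both was -0.24 with flavopiridol and -1.06 with IBET151. The inhibitor libraries were less enriched, with 26.4% against 41.4% of tags in peaks for flavopiridol and 10.4% against 31.3% for IBET151. At equal list length, 72.7% and 74.0% of PU.1 peaks were called again. For p65, 79.3% of 95723 peaks were called again with IBET151 at 1 h (median log2 ratio -0.18, libraries of 19.6 and 19.7 M tags). With flavopiridol at 6 h, 30.7% of 9214 p65 peaks were called again (median log2 ratio -0.42), between libraries with 5.71% and 3.23% of tags in peaks.

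Single libraries of other factors and marks completed the time courses. C/EBPa had 47337 peaks untreated and 49796 after 1 h of KLA, with 16677 gained and 14218 lost. H3K27ac went from 39024 to 45169 regions, with 14930 gained and 9065 lost. Serine 2-phosphorylated polymerase had 369 and 1394 peaks, from libraries with 0.43% and 0.68% of tags in peaks. The H4K5ac lists of bone marrow-derived macrophages used another genome build and were compared with each other only: 74470 regions untreated, 53968 at 1 h, 55347 at 6 h and 30331 at 18 h, from 10.8, 1.70, 1.70 and 0.903 M tags. Their labels name an antibody against H4K8ac.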

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

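Added only after the results were seen were the tests with the common tag minimum, with matched constitutive regions, with pairs of at least 2.5 M untreated tags, with H4K8ac at gained regions, without regions called in every untreated siRNA library, and those of gene lists. Among the results that answer a comparison, 110 settings over 14 results kept the direction and the side of the threshold, or moved little, 25 moved a value, 9 turned a direction, 7 ended a call at the unadjusted threshold and 1 passed it. For gene lists and single regions the numbers were 219 alike, 26 weaker, 7 turned and 4 stronger. Where the text below gives no reason, the cause was not tested. Depth limits which weak regions reach the tag threshold, but it does not alone set how many were called: the IKK inhibitor library (8.55 M tags) called 30.2% of gained regions and the deeper DMSO library (9.76 M) 19.6%.

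H3K4me2 at gained regions differed by 5.75 to 8.35 points when each siRNA pair was left out, by 3.26 at equal list length (exact p = 0.00391) and by 3.86 in the 5 pairs with at least 2.5 M untreated tags (exact p = 0.312; fewer pairs). For H3K4me1 the range over left-out pairs was 6.25 to 8.96. Its unadjusted exact p became 0.0547 without siCtl (8.29), siMll3 (7.40), siSet1a (6.75), siSet1b (7.68), siSmyd2 (7.11) or siSmyd3 (6.25), with 8 pairs. The Mll difference for H3K4me2 turned to -0.038 (exact permutation p = 0.917) relative to untreated libraries and to -0.11 against siCtl alone.

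With the group number as a pairing, the exact sign-flip p was 0.125 for H4K8ac with KLA, the smallest that 4 pairs allow. It was 0.5, the smallest for 2 pairs, for the amanitin and flavopiridol comparisons of H4K8ac, H3K4me2 at 1 h and p65 peak number. For amanitin and H3K4me2 it was 1. Without the pairing by siRNA, the exact permutation p was 0.0234 for H3K4me2 and 0.0110 for H3K4me1. The H4K8ac difference was 1.42 at gained regions in place of induced p65 sites (exact permutation p = 0.0286). With flavopiridol the H4K8ac difference turned to -9.68 points as a share of sites called. Amanitin and H3K4me2 turned to 0.020 with overlap of 50% of the shorter region, 0.0038 at distal regions and 1.41 points as a share called, and ran from -0.11 to 0.10 when each replicate was left out. The 2 against 2 comparisons and the sign-flip test of 4 pairs cannot pass a threshold, so they say nothing about stability.

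Counts of gained regions moved most with the stricter set (634 for H3K4me2, 6915 for PU.1) and equal list length (11148 and 15810). Flavopiridol stood at 70.6% of DMSO at equal list length and 67.7% with a common tag minimum. The IKK inhibitor stood at 148% with overlap of 50% of the shorter region, 132% at equal list length, 230.4% with a common minimum and 56.9% in the stricter set. The share of p65 at gained relative to all constitutive regions was 180% in the stricter set, which restricted the gained regions only, and 37.2% with group 2. With overlap of 50%, the stricter set and equal list length in turn, PU.1 peaks called again were 37.1%, 65.5% and 72.7% with flavopiridol and 34.4%, 62.9% and 74.0% with IBET151. For p65 they were 26.1%, 43.7% and 39.4% with flavopiridol and 74.3%, 94.8% and 79.8% with IBET151. The IBET151 difference for H4K8ac was 0.49, 0.54 and 0.26.

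By density, directions turned for H4K8ac at gained regions near granulocyte genes (-0.215 tags per kb) and H3K4me1 near fibroblast genes (-0.00543). They also turned for H4K8ac at induced p65 sites near macrophage identity (-8.26), cholesterol (-3.42), housekeeping (-1.21) and lymphocyte genes (-5.20). H3K4me1 near fibroblast genes ran from -1.56 points without siSet1b to 4.69 without siCtl.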

Other observations

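Tests of the regions lost or kept in every siRNA library, of the lost regions with flavopiridol and of the 14 strong regions were chosen only after the result was seen, and so were the gene-list tests of H4K8ac. Strong gained regions were called for H3K4me2 at 54.3% at KLA 1 h, 96.4% at 24 h and 88.5% at 48 h. The antiviral gene Mx2 had an intronic gained region (chromosome 16, 97769024 to 97772070) with 39.6 tags at 6 h, 55.9 at 24 h and 74.9 at 48 h. At Acsl1 the p65 counts were 22.5 at 1 h, 280.8 at 6 h and 753.8 at 24 h. The IKK inhibitor library for H3K4me2 held high counts at some regions that were weak elsewhere, with 120.5 tags near Lyz1 (15.3 at KLA 6 h) besides Elane. H4K8ac at gained regions near the remaining lists was called at 42.2% with KLA against 25% (immediate early), 34.7% against 24.4% (macrophage), 35.2% against 21.6% (cholesterol), 19.4% against 0% (housekeeping), 22.5% against 25% (lymphocyte), 14.6% against 10.4% (granulocyte) and 3.12% against 0% (fibroblast), and none of these passed adjustment. Of 20 groups of libraries searched for a value far from the others, 0 held one, where chance gives 5%. The KLA differences of H3K4me2 and H3K4me1 across the siRNA pairs differed by -0.78 points (n = 9, exact p = 0.820).

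More gained regions were called with KLA than without across the siRNA pairs, and deeper KLA libraries are a technical candidate explanation. Matched constitutive regions would then gain as much, but gained regions exceeded them by 3.61 points for H3K4me2 (8 of 9 pairs, exact sign-flip p = 0.0156) and 4.93 for H3K4me1 (9 of 9, exact p = 0.00391). Near inflammatory, interferon and NF-kB genes (148 regions) the excess was 15.8 points for H3K4me2 and 22.9 for H3K4me1 (n = 9 pairs, 9 of 9 each, exact p = 0.00391). None of these p-values was adjusted. Depth therefore does not account for the whole difference, though matched regions themselves differed by 3.38 and 2.84 points over all gained regions. A methylation response to KLA may account for the rest, as a hypothesis: the regions were defined on the time-course libraries, but the pattern was seen and weighed in the same siRNA libraries.

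Fewer gained regions were called for H3K4me2 with flavopiridol than with DMSO, and lower depth or enrichment of 1 library could account for that. Matched constitutive regions stood at 71.9% of DMSO (bootstrap interval 69.3 to 74.7) and gained regions at 50.6% (48.2 to 53.2). This does not exclude a loss common to weak regions, because matched regions were called more often with DMSO than gained ones. The gained value was also higher at equal list length and with a common tag minimum. Strong gained regions were called at 90.1% with DMSO and their matched regions at 88.2%. There flavopiridol stood at 48.3% of DMSO against 91.7% at matched regions. A return to the untreated pattern stays open: lost regions stood at 64.4% of DMSO, but the interval of 52.4 to 79.0 holds the value of matched regions. An effect of flavopiridol on newly gained regions may remain, but with 1 library per condition it cannot be separated from other differences between the libraries.

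Some gained regions, 51 in all, were called in all 9 untreated siRNA libraries, and the filter against clonal tags may have removed them from the untreated list. Their median clonal fold was 0.8 against 0.762 in matched regions, but 51 exceeds the 45 regions removed, which leaves this open. For the 14 strong ones the fold was 1.2 against 0.988. For 23 lost regions called in all 9 KLA siRNA libraries it was 1.11 against 0.998, with 42 removed. The values of these 14 and 23 regions met the prediction for the filter. However, the fold was taken in the library that kept the regions and lay below the limit of 2. Matching was on density alone, while 78.6% of the 14 and 65.2% of the 23 lay within 3 kb of a start. A higher fold therefore does not show that the filter removed them. A gain with KLA at the 51 regions was the biological alternative, and their density relative to constitutive regions differed by -0.14 on the log2 scale (n = 9 pairs, 2 of 9 higher, exact p = 0.102). A value at or below 0 had been set in advance to exclude a gain, but that bound was wrong, because the regions were picked for being called in the untreated libraries of the same pairs. In the untreated amanitin-experiment libraries, which had no part in the choice, 37 and 36 of the 51 were called.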
